A study of Homo sapiens with 12 samples.

How the data were processed

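RNA was measured on 12 Affymetrix PrimeView arrays, which read the 3' part of human transcripts with sets of short probes. The arrays covered U87EGFRvIII cells (U87vIII), an established glioblastoma line that expresses a truncated and constantly active form of the epidermal growth factor receptor, and normal human astrocytes (NHA), which are primary cells. Each cell type received the solvent DMSO or 5 uM LXR-623, a synthetic agonist of the liver X receptors (LXR), for 24 h, with 3 arrays per group and 4 groups. The authors normalized all arrays by robust multiarray average (RMA) with the affy package (version 1.48) in R (version 3.2.2), and the deposited values are log2 intensities that run from 2.08 to 13.9. They were used as they stand, with no further scaling.

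The deposited table holds 49395 probe sets. Of these, 102 were controls, 44994 paired with a single gene symbol, 1832 with several symbols and 2473 with none, where 6 of the controls also paired with a single symbol and are counted in both. After the controls and 70 sex-linked probe sets were left out to keep the primary cells free of personal detail, 44918 remained, for 18106 genes. Where a gene had several probe sets, as 11722 genes had, the probe set with the highest mean over all 12 arrays stood for it. No count of molecules lies behind an array value, so the precision was limited by the number of arrays.

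Differences were tested with limma (version 3.58.1) in R (version 4.3.3), in a single linear model with 1 mean per group over all 12 arrays and empirical Bayes moderation. The residual degrees of freedom were 8, the prior added 3.75, and the total was 11.8. The model gave 4 contrasts: LXR-623 against DMSO in U87vIII, LXR-623 against DMSO in NHA, the difference between these effects (U87vIII effect minus NHA effect), and U87vIII DMSO against NHA DMSO. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the 18106 genes of each contrast, and a gene was called at an adjusted p under 0.05. Values are log2 differences of group means ± the standard error (SE) of the model, with 3 arrays per group, and intervals are 95% confidence intervals. An exact permutation test of 3 arrays against 3 cannot give a p below 0.1, so no single-gene permutation test could pass the threshold. The labels do not say that the replicates came from separate cultures, so every p-value measures only the spread between these arrays, which may be technical.

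Gene lists were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the 24 lists of each contrast. The lists, with measured of fixed members, were LXR target genes (19 of 21), cholesterol biosynthesis enzymes (16 of 20), sterol uptake and sensing (12 of 15), fatty acid synthesis and desaturation (17 of 18), lipid storage and lipolysis (22 of 22), PPAR target genes (13 of 15), ATF4 and integrated stress response (23 of 23), endoplasmic reticulum chaperones and unfolded protein response (19 of 19), pro-apoptotic genes (18 of 20), p53 target genes (22 of 24), mitosis genes (23 of 23), DNA replication genes (30 of 31), NF-kB and inflammatory genes (23 of 26), interferon-stimulated genes (22 of 24), glycolysis and hypoxia genes (25 of 28), growth factor and MAPK output genes (20 of 21), mesenchymal glioma markers (12 of 14), genes of the 9p21 region lost in U87 cells (3 of 3), and markers of astrocytes (19 of 19), neurons (14 of 14), the oligodendrocyte lineage (11 of 12), microglia and macrophages (13 of 13), endothelium (10 of 10), and fibroblasts and pericytes (12 of 12). In all, 409 of 438 list members were measured here, and the others were not analysed. Members were also counted at an adjusted p under 0.05 over all genes and adjusted over the list alone.

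The contrasts, the thresholds, the lists, the alternatives and the rule for naming genes were chosen before the data were examined. The rule named 17 key genes whatever their values, of which 13 were measured. It added, per contrast, the 8 largest positive and the 8 largest negative log2 values among called genes whose arrays did not overlap between the groups (overlap was not asked about for the difference of effects) and whose brighter group mean lay above the 40th percentile of gene means. It also added up to 4 called members per list and contrast, those with the smallest p. Genes with common germline deletions or null alleles, HLA class II genes and unnamed loci were never named. Many genes that the rule picked, but whose calls were lost without a single array, are not named in the text.

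The procedure was tested on simulated data of the same size with 200 changed genes. At 1.25-fold, 1.5-fold and 2-fold changes it recovered 47.8%, 88.1% and 100% of the genes planted in the U87vIII contrast, and 47.8%, 94.0% and 100% in NHA, with 4.85% and 7.47% of calls false. In the difference of effects it recovered 7.46%, 76.1% and 100%, with 1.61% false, and in the baseline contrast 53.7%, 91.0% and 100%, with 4.12% false. Of 24 simulated lists of 20 genes per contrast, the 12 shifted by 0.2 were called and the other 12 were not. The simulated noise was drawn separately for each gene, so members of these lists were not correlated. The simulation therefore does not show how often the list test calls wrongly when members move together. Nor do its false shares for single genes cover trends shared by many genes. In the real arrays 29.7% of the within-group variance lay on 1 axis. The baseline simulation also changed only 200 genes, while 67.4% of genes were called in the data.

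The alternatives set beforehand were the mean of a gene's probe sets, every probe set tested by itself, the dimmest 40% of genes left out (a mean log2 value under 5.94), each array shifted to a common median, quantile normalization within each cell type, eBayes with trend and robust moderation, the replicate number as a block, a 2-fold minimum, an adjusted p under 0.01, a model of only the 6 arrays compared, each array left out in turn, camera with an estimated correlation, and fry. Another pair was chosen after seeing the data: leaving out the 2 arrays at the ends of the leading axis of within-group deviations, and removing that axis from all arrays. The treatment labels were also regrouped, in all 10 splits of each set of 6 arrays and in 100 drawn splits for the difference of effects. Control probe sets, probe sets with several symbols or none, and sex-linked genes were left out of the gene tests because they name no single gene or could identify a person.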

Results

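Expression was measured on 12 arrays in 4 groups of 3: NHA with DMSO, NHA with LXR-623, U87vIII with DMSO and U87vIII with LXR-623. Array medians lay between 6.29 and 6.36 on the log2 scale. Across probe sets, arrays of a group correlated at 0.997 to 0.999, arrays of different treatments in a cell type at 0.996 to 0.998, and arrays of different cell types at 0.919 to 0.929. Controls for background with 20 G or C bases per probe read 6.23 and 6.06 in NHA (DMSO and LXR-623) and 5.90 and 5.87 in U87vIII, a log2 change of -0.18 ± 0.051 in NHA (adjusted p = 0.21) and -0.04 ± 0.051 in U87vIII (adjusted p = 0.87). In NHA every DMSO array (6.18 to 6.29) read above every LXR-623 array (6.01 to 6.11). The adjusted p therefore does not show that the NHA background stayed level. Background controls with 13 G or C bases read 3.09 and 3.05 in NHA and 3.00 and 3.01 in U87vIII, so the background of a probe set depends on its bases, which the data do not give. Along the leading axis of deviations from the group means, which held 29.7% of the within-group variance, NHA DMSO 2 (9.39) and U87vIII LXR-623 1 (-11.3) lay farthest apart.

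The effect of the LXR agonist was first examined in the glioblastoma cells. In U87vIII, LXR-623 raised ABCA1, the transporter that exports cholesterol to apolipoprotein A-I, by 2.14 ± 0.0474 on the log2 scale (4.42-fold, adjusted p = 2.74e-10). MYLIP, the ubiquitin ligase that marks LDL receptors for degradation, rose by 2.19 ± 0.101 (4.58-fold, adjusted p = 6.85e-07). SREBF1, which encodes the transcription factor of fatty acid synthesis SREBP-1, rose by 1.24 ± 0.0768, and LPCAT3, which places polyunsaturated chains in phospholipids, by 0.90 ± 0.0551 (adjusted p = 5.79e-06 for each). FASN, the fatty acid synthase, rose by 0.71 ± 0.0571, and SCD, the stearoyl-CoA desaturase, by 0.41 ± 0.0504. The largest increase of any named gene was that of SPINK1, a secreted trypsin inhibitor, at 2.37 ± 0.172 (5.18-fold, adjusted p = 1.99e-05).

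Among the LXR target genes in U87vIII, 6 of 19 measured members rose and none fell, and adjusted over the list alone 7 rose (median 0.13, adjusted p = 2.71e-10). The list kept its call with an estimated correlation (adjusted p = 0.00514). Several classical targets were not called over all genes. ABCG1, a cholesterol exporter to HDL, read -0.12 ± 0.119 (95% interval -0.38 to 0.14, adjusted p = 0.781), and its 5 probe sets lay between -0.12 and 0.08. Its level of 4.65 in U87vIII DMSO lay within the range of the background controls. APOE, the main apolipoprotein of the brain, read 0.02 (adjusted p = 0.924), and NR1H3, which encodes LXR alpha itself, 0.33 ± 0.0954 (adjusted p = 0.115, but 0.0139 adjusted over the list alone). EGFR read -0.10 ± 0.185 (adjusted p = 0.909).

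Fatty acid synthesis and desaturation genes rose as a list in U87vIII, with 8 of 17 members higher and none lower, and 10 higher adjusted over the list alone (median 0.18, adjusted p = 3.3e-10, and 0.00514 with an estimated correlation). Beyond FASN and SCD, MID1IP1, an activator of acetyl-CoA carboxylase, rose by 0.66 ± 0.1 (adjusted p = 0.0038) and LPIN1, a phosphatidate phosphatase, by 0.50 ± 0.0453 (adjusted p = 0.000112). Of the 16 cholesterol biosynthesis enzymes, 1 rose and none fell, with 2 higher adjusted over the list alone, and the list was not called (median 0.02, adjusted p = 0.201). The enzyme that rose lost its call without any 1 of the U87vIII arrays but LXR-623 3 (adjusted p up to 0.124, without DMSO 3). HMGCS1, the hydroxymethylglutaryl-CoA synthase, read -0.08 ± 0.0594 (95% interval -0.21 to 0.05, adjusted p = 0.679). Sterol uptake and sensing genes rose with 3 of 12 members higher, and 5 adjusted over the list alone (median 0.14, adjusted p = 9.49e-06), a call that was lost at an adjusted p = 0.147 with an estimated correlation. Its risen members were NPC1, which releases cholesterol from lysosomes (0.58 ± 0.0699), VLDLR, a lipoprotein receptor (0.45 ± 0.0749), and INSIG1, which holds SREBPs in the endoplasmic reticulum (0.27 ± 0.0481). SREBF2, which encodes the transcription factor of cholesterol synthesis, read 0.05 (adjusted p = 0.898).

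Stress response genes also rose in U87vIII. In the ATF4 and integrated stress response list 5 of 23 members rose and none fell, and 11 rose adjusted over the list alone (median 0.15, adjusted p = 9.04e-09, but adjusted p = 0.102 with an estimated correlation). They included CTH, which makes cysteine from cystathionine (0.77 ± 0.11), SLC3A2, the shared heavy chain of amino acid transporters (0.63 ± 0.0467), and the secreted glycoprotein gene STC2 (0.41 ± 0.0511). Endoplasmic reticulum chaperones and unfolded protein response genes rose with 3 of 19 members higher, and 10 adjusted over the list alone (median 0.15, adjusted p = 2.61e-08, and 0.0246 with an estimated correlation), led by the chaperone genes DNAJB9 (0.68 ± 0.0654) and SDF2L1 (0.39 ± 0.0545). Glycolysis and hypoxia genes rose with 4 of 25 members higher, and 8 adjusted over the list alone (median 0.04, adjusted p = 4.94e-05, but adjusted p = 0.102 with an estimated correlation), among them the glucose transporter SLC2A1 (0.36 ± 0.0533). The other 3, VEGFA, PDK1 and NDRG1, all lost their calls without U87vIII DMSO 1 (adjusted p = 0.0605, 0.119 and 0.129) or U87vIII LXR-623 1 (adjusted p = 0.0519, 0.105 and 0.125), which left 1 of 25.

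DNA replication genes fell as a list in U87vIII by a median of -0.09, with 1 of 30 members lower, and 6 adjusted over the list alone (adjusted p = 9.38e-06, but adjusted p = 0.102 with an estimated correlation). The only replication gene called over all genes lost its call without any 1 of the 6 U87vIII arrays. Mitosis genes fell by a median of -0.04 with none of 23 members called on either scale (adjusted p = 0.0269, but adjusted p = 0.59 with an estimated correlation). That mitosis call was lost without U87vIII DMSO 1 (adjusted p = 0.0653) or U87vIII DMSO 3 (adjusted p = 0.0732). Fibroblast and pericyte markers fell by a median of -0.18, with 1 of 12 higher and 1 lower, and 6 lower adjusted over the list alone (adjusted p = 0.00183, but adjusted p = 0.102 with an estimated correlation). COL1A1, the main chain of type I collagen, fell by 0.51 ± 0.0472. The member called higher lost its call without any 1 of the U87vIII arrays but LXR-623 3. Mesenchymal glioma markers rose by a median of 0.03 with 1 of 12 higher, the collagen crosslinking enzyme LOX (0.27 ± 0.0431), and 3 adjusted over the list alone (adjusted p = 0.0324, but adjusted p = 0.187 with an estimated correlation). That call was lost without U87vIII DMSO 1, DMSO 3, LXR-623 1 or LXR-623 3 (adjusted p = 0.0653, 0.0725, 0.0624 and 0.0779).

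Inflammatory genes contributed some of the larger single changes in U87vIII. IL1B, which encodes interleukin-1 beta, rose by 1.21 ± 0.0648 (2.31-fold, adjusted p = 2.55e-06), PTGS2, the inducible cyclooxygenase, by 1.09 ± 0.0801 (adjusted p = 2.01e-05), IL1A by 0.66 ± 0.103 and the cytokine gene LIF by 0.33 ± 0.0511. These were the 4 of 23 NF-kB and inflammatory genes that rose. Adjusted over the list alone 5 rose and 3 fell, and the list was not called (adjusted p = 0.0599). MMP3, a matrix metalloproteinase, rose by 1.24 ± 0.108, and GDF15, a stress-induced cytokine, by 0.76 ± 0.068. ATP6V0D2, a subunit of the vacuolar proton pump, rose by 1.43 ± 0.117, PNLIPRP3, of the pancreatic lipase family, by 1.36 ± 0.0837 and TMEM156, a membrane protein gene, by 1.27 ± 0.128. The DMSO levels of SPINK1 (5.00), MYLIP (5.44), ATP6V0D2 (5.67), TMEM156 (4.89) and PTGS2 (4.87), and that of IL1A lay within the range of the background controls (3.00 to 5.90), so the sizes of their changes are lower bounds if these levels are background.

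Among the named genes the largest decreases in U87vIII were of THBS1, which encodes the matrix glycoprotein thrombospondin-1 (-0.90 ± 0.112, 1.86-fold lower, adjusted p = 0.00117), the linker histone gene H1-3 (-0.88 ± 0.185, adjusted p = 0.0257) and LRRC17 (-0.85 ± 0.0798). The call of H1-3 was lost without U87vIII DMSO 1, DMSO 3, LXR-623 1 or LXR-623 2 (adjusted p up to 0.104, without DMSO 3). Another linker histone gene, H1-1 (-0.83 ± 0.14), the vasoconstrictor peptide gene EDN1 (-0.79 ± 0.134), the vascular ligand gene ANGPT1 (-0.79 ± 0.0622) and the actin-associated genes SHROOM2 (-0.76 ± 0.0591) and SYNPO (-0.73 ± 0.0838) also fell. EDN1 read 5.33 with LXR-623, within the range of the background controls, so its size is a lower bound if that level is background. Of the 20 growth factor and MAPK output genes 2 rose and 3 fell, with 5 in each direction adjusted over the list alone, and the list was not called (median -0.0035, adjusted p = 0.853). Both members that rose lost their calls without single U87vIII arrays: LXR-623 2 for 1 (adjusted p = 0.0526), and DMSO 1 or LXR-623 3 for the other (up to 0.054). The receptor tyrosine kinase gene EPHA2 fell by 0.50 ± 0.0479 and the EGFR ligand gene HBEGF by 0.41 ± 0.0626.

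The other lists were not called in U87vIII. Of 22 lipid storage and lipolysis genes 1 rose, CIDEA of the lipid droplet (0.63 ± 0.0595), and 1 fell, the lipolysis inhibitor G0S2 (-0.38 ± 0.0639, at 5.11 and 4.73 within the range of the background controls), with the same counts adjusted over the list alone (adjusted p = 0.519). Of 18 pro-apoptotic genes 1 rose and 2 fell, and 1 and 3 adjusted over the list alone (adjusted p = 0.546), with PMAIP1, the BH3-only protein NOXA, lower by 0.36 ± 0.0414. Of 22 p53 target genes 4 rose, GDF15 and TP53INP1 (0.34 ± 0.0556) among them, and 4 rose and 2 fell adjusted over the list alone (adjusted p = 0.0705). Of 13 PPAR target genes 1 rose, and 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.837). No interferon-stimulated gene of 22 was called, and 1 fell adjusted over the list alone (median 0.01, mean -0.03, test direction down, adjusted p = 0.55). Among cell type markers 1 of 13 for microglia and macrophages rose (adjusted p = 0.853), 1 of 14 for neurons fell (median 0.01, mean -0.004, test direction down, adjusted p = 0.853), and none was called of 19 for astrocytes (adjusted p = 0.519), 11 for the oligodendrocyte lineage (median -0.02, mean 0.0003, test direction down, adjusted p = 0.853) or 10 for endothelium (adjusted p = 0.58). Adjusted over the list alone the microglia and neuron counts stayed at 1, 1 astrocyte marker rose and 1 fell, and none of the others was called. Of the 3 genes of the 9p21 region none was called on either scale (adjusted p = 0.915). Leaving out single arrays took the counts over all genes as low as 2 for p53 targets, 0 and 1 (higher and lower) for pro-apoptotic genes, and 0 for PPAR targets, neurons and microglia.

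By limma 309 genes were higher and 173 lower in U87vIII with LXR-623, 2.66% of the 18106 tested, with 11 at least 2-fold higher and a median size of 0.36 on the log2 scale. With a single array fewer the counts fell. Without U87vIII DMSO 1, DMSO 3, LXR-623 1 and LXR-623 2 in turn, 177, 182, 181 and 174 genes were higher, and without DMSO 1, DMSO 2, LXR-623 2 and LXR-623 3, 105, 107, 101 and 111 were lower. Apart from H1-3, VEGFA, PDK1 and NDRG1, every U87vIII gene named above with a change kept its call in each of these 6 refits. That reflects which genes are named above. Of the 59 called U87vIII genes picked by the naming rule, 42 kept their calls in all 6.

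**Figure D1:**
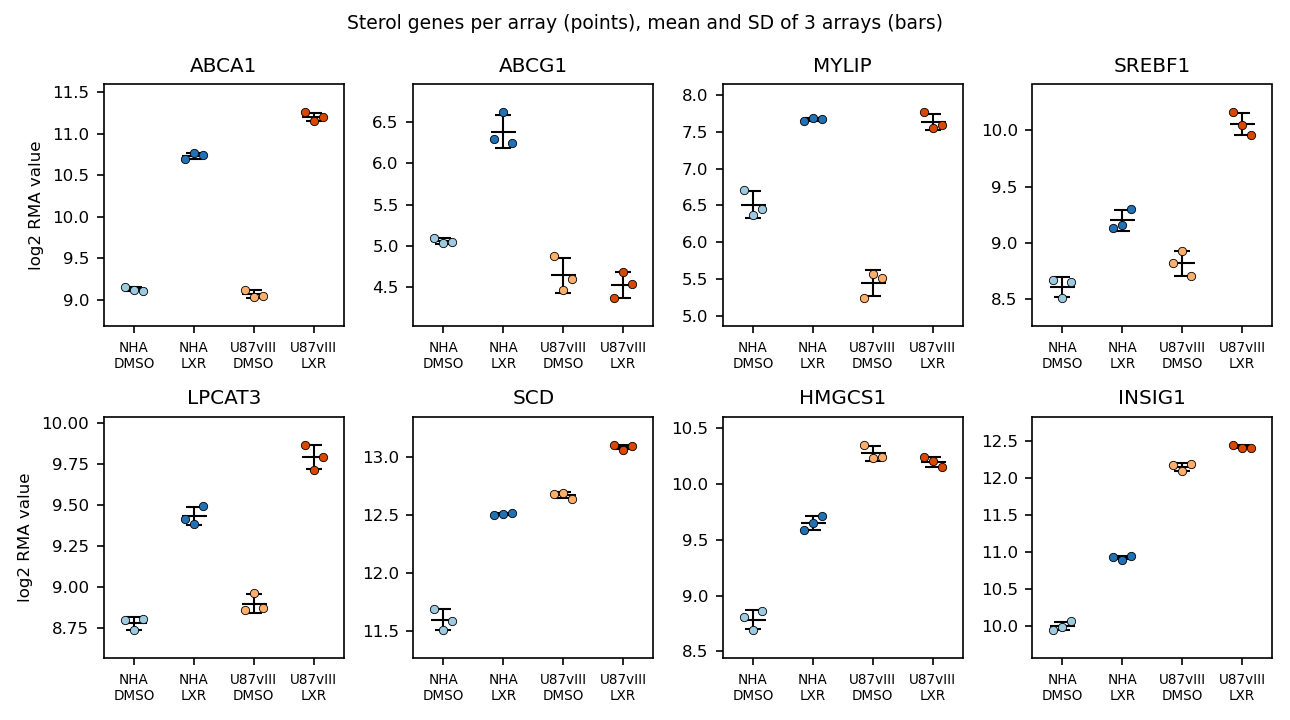
Log2 RMA value of 8 genes (a panel each, y axis) in the 4 groups (x axis), with a point per array and the mean with SD of 3 arrays. ABCA1 rose in U87vIII (2.14) and NHA (1.61), whereas ABCG1 rose in NHA (1.32) and not in U87vIII (-0.12), and HMGCS1 rose in NHA (0.86) from a lower DMSO level than in U87vIII (-0.08).

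The same treatment was then examined in normal human astrocytes. In NHA, LXR-623 raised ABCA1 by 1.61 ± 0.0474 (3.06-fold, adjusted p = 7.54e-09), ABCG1 by 1.32 ± 0.119 (2.5-fold, adjusted p = 0.000198) and MYLIP by 1.16 ± 0.101 (2.23-fold, adjusted p = 0.000183). All 5 probe sets of ABCG1 were called, from 1.32 to 3.75, so the brightest probe set gave the smallest change. The NHA DMSO level of ABCG1 (5.06) lay within the range of the background controls (3.09 to 6.23), so the 2.5-fold is a lower bound if that level is background. Genes of cholesterol and fatty acid synthesis rose together with these targets: INSIG1 by 0.92 ± 0.0481 (1.9-fold, adjusted p = 2.84e-06), SCD by 0.92 ± 0.0504 (1.89-fold, adjusted p = 3.49e-06) and HMGCS1 by 0.86 ± 0.0594 (1.82-fold, adjusted p = 3.22e-05).

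Of the LXR target genes in NHA 7 of 19 rose and none fell, and 7 rose and 1 fell adjusted over the list alone (median 0.04, adjusted p = 1.64e-07, and 0.014 with an estimated correlation). Besides those given above these were LPCAT3 (0.65 ± 0.0551), SREBF1 (0.59 ± 0.0768) and FASN (0.47 ± 0.0571). APOE read -0.01, NR1H3 0.09 (adjusted p = 0.754) and EGFR 0.14 (adjusted p = 0.818), none of them called. Cholesterol biosynthesis enzymes rose by a median of 0.40, with 11 of 16 members higher and none lower, and 14 higher adjusted over the list alone (adjusted p = 5.58e-27, and 0.0133 with an estimated correlation). Examples beside HMGCS1 were IDI1, the isopentenyl diphosphate isomerase (0.58 ± 0.0582), MSMO1, a sterol C4 oxidase (0.53 ± 0.0432), and ACAT2, which makes acetoacetyl-CoA (0.44 ± 0.0436). SREBF2 itself was not called (0.22 ± 0.0804, adjusted p = 0.245).

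Fatty acid synthesis and desaturation genes rose in NHA with 9 of 17 higher on either scale, over all genes and adjusted over the list alone (median 0.28, adjusted p = 2.68e-18, and 0.00128 with an estimated correlation). The desaturase genes FADS2 (0.69 ± 0.0575) and FADS1 (0.66 ± 0.0509), and LPIN1 (0.51 ± 0.0453), were among them. Sterol uptake and sensing genes rose with 4 of 12 higher, and 6 adjusted over the list alone (median 0.15, adjusted p = 1.64e-07, but adjusted p = 0.0957 with an estimated correlation), including the lipoprotein receptor gene LRP8 (0.55 ± 0.072). Without NHA DMSO 1, DMSO 2, DMSO 3, LXR-623 2 or LXR-623 3 only 2 of the 4 were called. PPAR target genes rose by a median of 0.06 with 1 of 13 higher, the fatty acid carrier FABP3 (0.94 ± 0.154, adjusted p = 0.0168), and 2 adjusted over the list alone (adjusted p = 0.0347, but adjusted p = 0.487 with an estimated correlation). The list's call was lost without NHA DMSO 2, DMSO 3 or LXR-623 3 (adjusted p = 0.113, 0.104 and 0.112), and that of FABP3, at 6.18 in NHA DMSO, without DMSO 2, LXR-623 2 or LXR-623 3 (adjusted p up to 0.081, without DMSO 2).

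Mitosis genes rose in NHA by a median of 0.25, with 4 of 23 higher and none lower, and 20 higher adjusted over the list alone (adjusted p = 1.31e-18, and 0.0184 with an estimated correlation). CENPA, the histone variant of centromeres, rose by 0.44 ± 0.066, and the spindle gene HMMR by 0.38 ± 0.0471. CENPA in NHA DMSO (6.20) lay at the upper end of the background controls (6.23). DNA replication genes rose by a median of 0.16, with 6 of 30 higher and 17 adjusted over the list alone (adjusted p = 1.36e-11, and 0.0184 with an estimated correlation), among them GINS4 of the replicative helicase (0.44 ± 0.0555). Without single arrays fewer members were called: 2 mitosis genes without NHA DMSO 2, LXR-623 2 or LXR-623 3, and 1 replication gene without these or NHA DMSO 1. Growth factor and MAPK output genes rose by a median of 0.15, with 4 of 20 higher and 12 adjusted over the list alone (adjusted p = 1.54e-09, and 0.0177 with an estimated correlation). DUSP6, a phosphatase of ERK, rose by 0.37 ± 0.0483. The other 3, DUSP5, SPRY2 and HBEGF, lost their calls without NHA DMSO 2 (adjusted p = 0.116, 0.118 and 0.119), DMSO 3 (0.0607, 0.0809 and 0.0829), LXR-623 2 (0.116, 0.118 and 0.115) or LXR-623 3 (0.092, 0.096 and 0.103), which left 1 of 20.

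ATF4 and integrated stress response genes fell in NHA by a median of -0.21, with 5 of 23 lower and none higher, and 11 lower adjusted over the list alone (adjusted p = 1.45e-11, and 0.0478 with an estimated correlation). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, fell by 0.40 ± 0.0565 (adjusted p = 0.00586), and SLC7A11, the cystine importer, by 0.38 ± 0.0546 (adjusted p = 0.00725). Without any 1 of the NHA arrays but LXR-623 3, only 2 of the 5 were called. Endoplasmic reticulum chaperones and unfolded protein response genes rose by a median of 0.05 with no member of 19 called and 2 higher adjusted over the list alone (adjusted p = 0.028, but adjusted p = 0.283 with an estimated correlation). That call was lost without NHA DMSO 2 or NHA LXR-623 1 (adjusted p = 0.152 and 0.0883). Among the named genes the largest decrease in NHA was of TXNIP, a glucose-responsive inhibitor of thioredoxin (-0.49 ± 0.0447, 1.41-fold lower, adjusted p = 0.000201).

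The remaining lists were not called in NHA. NFIA, a transcription factor of astrocyte development, rose by 0.59 ± 0.0826 and was the only 1 of 19 astrocyte markers called (both NHA levels lay within the range of the background controls), with 1 higher and 1 lower adjusted over the list alone (median -0.02, mean 0.001, test direction down, adjusted p = 0.916). Of 22 lipid storage and lipolysis genes 1 fell, and 2 rose and 3 fell adjusted over the list alone (adjusted p = 0.689). None was called of 18 pro-apoptotic genes (adjusted p = 0.889), 22 p53 target genes (adjusted p = 0.0839), 25 glycolysis and hypoxia genes (adjusted p = 0.354) or 12 mesenchymal glioma markers (adjusted p = 0.689), on either scale. Of 23 NF-kB and inflammatory genes none was called, and 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.694). Of 22 interferon-stimulated genes 1 fell, and 1 rose and 1 fell adjusted over the list alone (median -0.03, mean 0.01, test direction down, adjusted p = 0.986). Of the 3 genes of the 9p21 region 1 rose, and 1 rose and 1 fell adjusted over the list alone (median -0.02, mean 0.05, test direction up, adjusted p = 0.663). Of 14 neuron markers 1 rose, and 4 rose and 1 fell adjusted over the list alone (adjusted p = 0.438). None was called on either scale for the oligodendrocyte lineage (adjusted p = 0.837), microglia and macrophages (adjusted p = 0.149), endothelium (adjusted p = 0.443) or fibroblasts and pericytes (adjusted p = 0.409). Leaving out single arrays took the counts over all genes to 0 for lipid storage, interferon-stimulated, 9p21 and neuron genes, and left NFIA called.

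By limma 123 genes were higher and 35 lower in NHA with LXR-623, 0.873% of the 18106 tested, with 3 at least 2-fold higher and a median size of 0.38. The genes called lower had a median level of 6.16 against 8.76 for those called higher, and 13 of the 35 lay under the dim level of 5.94. The median of 6.16 lay between the NHA background controls with 20 G or C bases, 6.23 with DMSO and 6.06 with LXR-623. Without NHA DMSO 2, DMSO 3, LXR-623 2 and LXR-623 3 in turn, 61, 69, 49 and 47 genes were higher, and without DMSO 1, DMSO 2, DMSO 3, LXR-623 1, LXR-623 2 and LXR-623 3, 15, 9, 7, 17, 5 and 14 were lower. Apart from FABP3, DUSP5, SPRY2 and HBEGF, every NHA gene named above with a change kept its call in each of these 6 refits. That reflects which genes are named above. Of the 47 called NHA genes picked by the naming rule, only 24 kept their calls in all 6.

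The responses of the cell types overlapped in part. In both cell types 25 genes were higher, against 2.1 expected for independent sets, and 4 were lower, against 0.334 expected. The 25 included ABCA1, MYLIP, SREBF1, LPCAT3, SCD, FASN, INSIG1, LPIN1 and NPC1. The 4 lower genes were GBP1, H2BC4, OLFML2B and S100A4, named after their values were seen. H2BC4 in U87vIII (4.43 and 4.03) and OLFML2B in NHA (6.21 and 5.76) lay within the range of the background controls, so their signal there is not shown to be above background. CIDEA was higher in U87vIII (0.63) and lower in NHA (-0.31), and HBEGF lower in U87vIII (-0.41) and higher in NHA (0.34). The levels of CIDEA in NHA (5.47 and 5.15) and U87vIII DMSO (5.50) lay within the range of the background controls, so its signal in NHA is not shown to be above background. Their NHA calls, and that of NPC1, were lost without single NHA arrays: CIDEA and HBEGF without any 1 of the 6 (adjusted p up to 0.158 without LXR-623 2 and 0.119 without DMSO 2), and NPC1 without any but LXR-623 1 (up to 0.154 without LXR-623 2). Across all genes, which are not independent replicates, the log2 changes of the cell types correlated at r = 0.161 (rho = 0.155), and 64.5% of the 609 genes called in either cell type had log2 values of the same sign in both, against 55.9% of all genes. Without NHA DMSO 3, NHA LXR-623 2 or NHA LXR-623 3 the genes higher in both were 15, 14 and 14, and without any 1 of the 12 arrays 0 to 2 genes were lower in both.

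**Figure D2:**
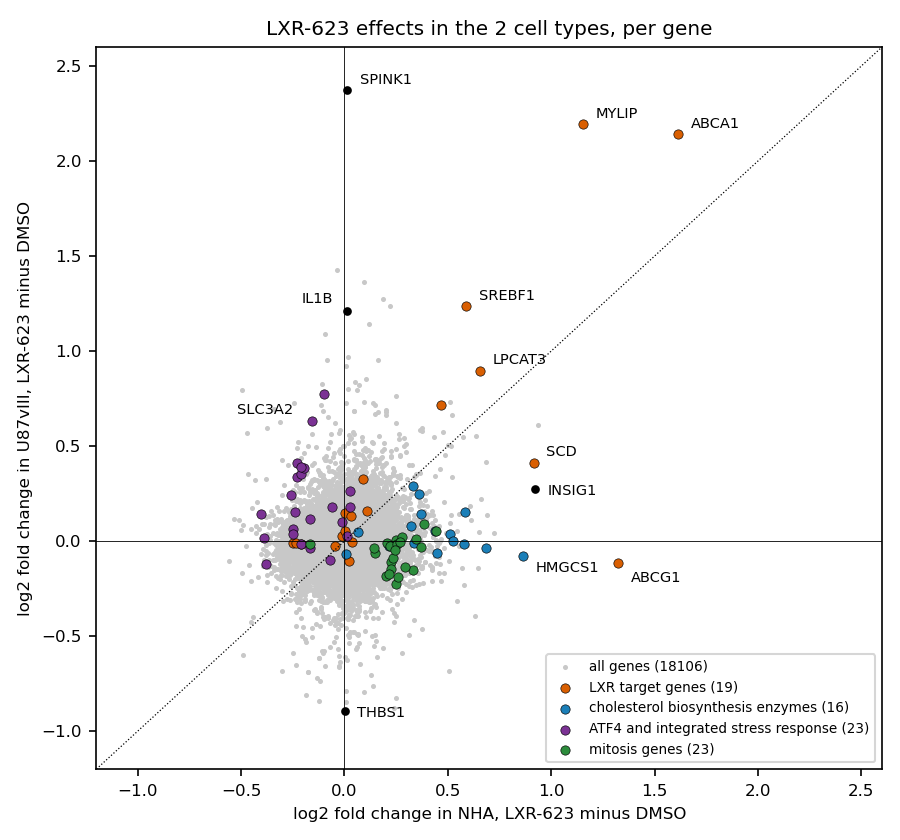
Log2 change with LXR-623 in NHA (x axis) against that in U87vIII (y axis) for 18106 genes (grey points), with 4 lists coloured, some genes labelled and a dotted line of equal change. ABCA1 (1.61 and 2.14) lies above the line by 0.53, HMGCS1 (0.86 and -0.08) and the other cholesterol biosynthesis enzymes (medians 0.40 and 0.02) lie below it, and SPINK1, at background in NHA, lies above it.

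The test of the difference asked whether the cell types responded unequally to LXR-623. The effect on ABCA1 was larger in U87vIII by 0.53 ± 0.0671 (adjusted p = 0.00315) and that on MYLIP by 1.04 ± 0.143 (adjusted p = 0.00622), while that on ABCG1 differed by -1.44 ± 0.168 (adjusted p = 0.00191). Of the LXR target genes 3 of 19 had a higher and 2 a lower effect in U87vIII, and 5 and 2 adjusted over the list alone (median 0.14, adjusted p = 0.00662, but adjusted p = 0.0961 with an estimated correlation). The effect on SREBF1 was larger by 0.65 ± 0.109 (adjusted p = 0.0167), a call lost without NHA DMSO 3 or NHA LXR-623 2 (adjusted p up to 0.0584, without the latter). For LPCAT3 the difference was 0.24 ± 0.078 (95% interval 0.07 to 0.41, adjusted p = 0.215) and for FASN 0.25 ± 0.0808 (adjusted p = 0.225), neither called over all genes.

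Sterol synthesis responded less in U87vIII. Cholesterol biosynthesis enzymes had a median difference of -0.36, with 8 of 16 lower and none higher, and 10 lower adjusted over the list alone (adjusted p = 1.85e-17, and 0.0273 with an estimated correlation). HMGCS1 differed by -0.94 ± 0.084 (adjusted p = 0.000596), IDI1 by -0.59 ± 0.0823, MSMO1 by -0.52 ± 0.0611 and the squalene epoxidase gene SQLE by -0.51 ± 0.0644. INSIG1 (-0.65 ± 0.0681), SCD (-0.50 ± 0.0713) and FADS2 (-0.55 ± 0.0814) also had lower effects. Fatty acid synthesis and desaturation genes had a median difference of -0.10 with 3 of 17 lower, and 1 higher and 4 lower adjusted over the list alone (adjusted p = 0.0107, but adjusted p = 0.0989 with an estimated correlation).

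The stress and proliferation lists differed in the opposite sense to each other. ATF4 and integrated stress response genes had a median difference of 0.31, with 5 of 23 higher and none lower, and 17 higher adjusted over the list alone (adjusted p = 4.62e-20, and 0.0273 with an estimated correlation). Examples were SLC3A2 (0.79 ± 0.0661), STC2 (0.64 ± 0.0723) and PCK2 (0.55 ± 0.0799). Mitosis genes had a median difference of -0.32, with 3 of 23 lower and 19 adjusted over the list alone (adjusted p = 4.49e-18, and 0.0273 with an estimated correlation). DNA replication genes had a median difference of -0.26, with 6 of 30 lower and 16 adjusted over the list alone (adjusted p = 3.54e-17, and 0.0273 with an estimated correlation), including GINS4 (-0.52 ± 0.0785) and the thymidylate synthase gene TYMS (-0.45 ± 0.072). The 3 mitosis genes, CDK1, TOP2A and MKI67, all lost their calls without NHA LXR-623 2 (adjusted p = 0.0693, 0.099 and 0.13), U87vIII DMSO 1 (0.0513, 0.0718 and 0.0974), NHA LXR-623 3 (0.0526, 0.0581 and 0.114) or U87vIII LXR-623 2 (0.0583, 0.0614 and 0.1). Only 2 of the 6 replication genes were called without any 1 array but NHA DMSO 3, U87vIII DMSO 2 or NHA LXR-623 1. Growth factor and MAPK output genes had a median difference of -0.14, with 3 of 20 lower and 7 adjusted over the list alone (adjusted p = 6.39e-06, but adjusted p = 0.0561 with an estimated correlation). Among these HBEGF differed by -0.75 ± 0.0885 and EPHA2 by -0.63 ± 0.0677.

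Smaller differences were found for 3 more lists. Glycolysis and hypoxia genes had a median difference of 0.05 with 2 of 25 higher, and 6 adjusted over the list alone (adjusted p = 6.63e-05, but adjusted p = 0.0805 with an estimated correlation). Endoplasmic reticulum chaperones and unfolded protein response genes had a median difference of 0.08 with 1 of 19 higher, and 3 adjusted over the list alone (adjusted p = 0.00537, but adjusted p = 0.131 with an estimated correlation). NF-kB and inflammatory genes had a median difference of 0.09 with 3 of 23 higher and 1 lower, and 4 and 1 adjusted over the list alone (adjusted p = 0.0356, but adjusted p = 0.0941 with an estimated correlation), with IL1B higher by 1.20 ± 0.0917 and PTGS2 by 1.19 ± 0.113. That list's call was lost without NHA DMSO 1, NHA DMSO 3, U87vIII DMSO 1, NHA LXR-623 3 or U87vIII LXR-623 3 (adjusted p = 0.0718, 0.0877, 0.0862, 0.0598 and 0.0574). The 2 glycolysis genes both lost their calls without any 1 array but NHA DMSO 1, U87vIII DMSO 1 or U87vIII LXR-623 2. The chaperone gene lost its call without NHA DMSO 1, NHA DMSO 3, U87vIII DMSO 2, NHA LXR-623 2, NHA LXR-623 3, U87vIII LXR-623 1 or U87vIII LXR-623 2, and the NF-kB gene called lower without any 1 array but NHA DMSO 1, U87vIII DMSO 3 or NHA LXR-623 1.

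Single genes outside the lists also differed. SPINK1 differed by 2.36 ± 0.244 (adjusted p = 0.000908), ATP6V0D2 by 1.47 ± 0.165, the aggrecanase gene ADAMTS5 by 1.29 ± 0.21 and PNLIPRP3 by 1.27 ± 0.118. In NHA with DMSO and LXR-623, SPINK1 read 2.99 and 3.00, PNLIPRP3 3.00 and 3.10, PTGS2 3.59 and 3.49, TMEM156 3.72 and 3.91, and ATP6V0D2 3.82 and 3.78. These levels lie at or near the controls with 13 G or C bases (3.09 and 3.05), so a fall there could not be seen, and a rise only above the background. ANO1, a calcium-activated chloride channel, differed by -1.19 ± 0.165, SHROOM2 by -0.90 ± 0.0836 and the small GTPase gene DIRAS3 by -0.87 ± 0.0897. The U87vIII levels of ANO1 (5.27 and 4.58) and ABCG1 (4.65 and 4.53) lay within the range of the background controls. Of the lipid storage and lipolysis genes CIDEA differed by 0.94 ± 0.0842 and G0S2 by -0.62 ± 0.0903, with the list not called (adjusted p = 0.392, 1 higher and 1 lower on either scale). The NHA and U87vIII DMSO levels of CIDEA and both U87vIII levels of G0S2 (5.11 and 4.73) lay within the range of the background controls, so the sizes of these differences are uncertain. Of the fibroblast and pericyte markers COL1A1 differed by -0.53 ± 0.0668, with the list not called (adjusted p = 0.0872, 1 lower, and 1 higher and 2 lower adjusted over the list alone). Of the pro-apoptotic genes PMAIP1 differed by -0.42 ± 0.0586, and of the neuron markers GAP43, a growth cone protein, by -0.43 ± 0.0677. Among lists that were not called, the median had another sign than the mean and the test for sterol uptake and sensing (median 0.01, mean -0.06), pro-apoptotic genes (0.004 and -0.006), p53 target genes (-0.01 and 0.02), interferon-stimulated genes (0.02 and -0.04) and the 9p21 genes (0.06 and -0.05). Their adjusted p-values were 0.36, 0.62, 0.646, 0.53 and 0.53. The other uncalled lists had an adjusted p of 0.196 (PPAR target genes), 0.195 (mesenchymal glioma markers), 0.53 (astrocyte markers), 0.404 (neuron markers), 0.703 (oligodendrocyte lineage), 0.36 (microglia and macrophages) and 0.853 (endothelium).

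By limma 66 genes had a higher and 113 a lower effect in U87vIII, 0.989% of the 18106 tested, with 11 and 4 differing at least 2-fold. Of the 451 genes called in U87vIII and not in NHA 111 had a called difference, and of the 127 called in NHA and not in U87vIII 36 had. Without NHA DMSO 3, U87vIII DMSO 2, NHA LXR-623 2, U87vIII LXR-623 1 and U87vIII LXR-623 2 in turn, 40, 42, 35, 41 and 40 genes had a higher effect. Lower effects fell to 72, 57, 60, 72, 52, 70, 43, 58, 73, 56 and 52 without NHA DMSO 1, 2 and 3, U87vIII DMSO 1, 2 and 3, NHA LXR-623 2 and 3, and U87vIII LXR-623 1, 2 and 3.

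**Figure D3:**
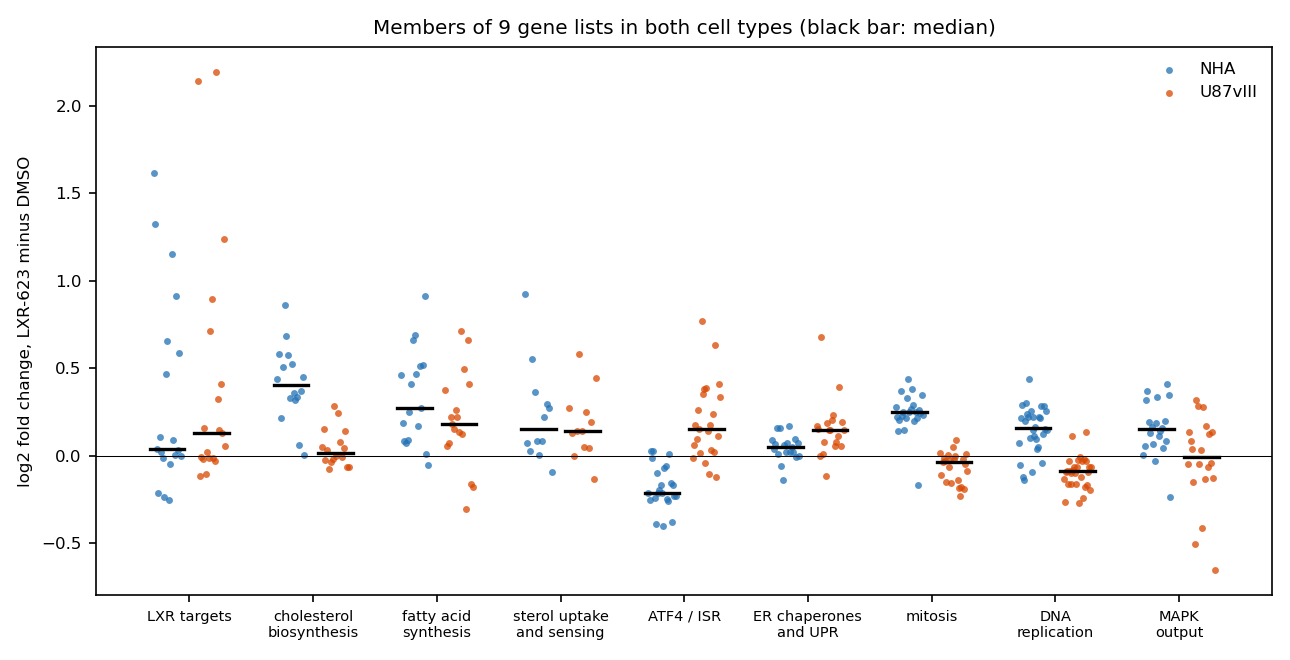
Log2 change with LXR-623 (y axis) of the members of 9 lists (x axis), a point per gene, NHA in blue and U87vIII in orange, with black bars at the medians. Cholesterol biosynthesis enzymes (medians 0.40 in NHA and 0.02 in U87vIII) and mitosis genes (0.25 and -0.04) were higher in NHA, and ATF4 and integrated stress response genes (-0.21 and 0.15) were higher in U87vIII.

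The baseline of the cell types was compared in DMSO. EGFR was higher in U87vIII by 3.23 ± 0.185 (9.36-fold, adjusted p = 7.29e-09), with 6 of its 8 probe sets called higher and 1, at a level of 3.71, called lower (-0.18). Of the 3 genes of the 9p21 region, all were lower on either scale (median -6.58, adjusted p = 0.0322, but adjusted p = 0.146 with an estimated correlation). The cell cycle inhibitor genes CDKN2A and CDKN2B differed by -7.38 ± 0.166 (167-fold lower) and -6.58 ± 0.075 (95.6-fold lower), and MTAP, of methionine salvage, by -0.28 ± 0.111 (adjusted p = 0.0434), a call lost without NHA DMSO 2, U87vIII DMSO 2 or U87vIII DMSO 3 (adjusted p up to 0.175, without the first). CHI3L1, a secreted chitinase-like glycoprotein, was higher in U87vIII by 7.06 ± 0.105 (133-fold) and IL13RA2, the decoy receptor of interleukin-13, by 6.48 ± 0.0695 (89.2-fold). FGF13, UGT8 of myelin galactolipid synthesis and the Notch ligand gene DNER were higher by 6.52 ± 0.105, 6.14 ± 0.0776 and 6.07 ± 0.108. In U87vIII DMSO CDKN2B read 2.96, at the controls with 13 G or C bases (3.00), and CDKN2A 4.44. In NHA DMSO CHI3L1 read 3.47, UGT8 3.53, FGF13 4.02, IL13RA2 4.66 and DNER 4.88, within the range of the background controls (3.09 to 6.23). The sizes of such differences are lower bounds if the dimmer level is background.

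Proliferation genes were higher in U87vIII. All 23 mitosis genes were higher on either scale (median 3.08, adjusted p = 3e-16, and 0.049 with an estimated correlation), with CENPA at 4.29 ± 0.066 and CDK1, the mitotic kinase, at 3.52 ± 0.0591. Of 30 DNA replication genes 29 were higher on either scale (median 2.57, adjusted p = 7.75e-17, and 0.0168 with an estimated correlation), with RRM2 of ribonucleotide reductase at 3.23 ± 0.0506. Of 22 p53 target genes 2 were higher and 19 lower on either scale (median -1.08, adjusted p = 7.97e-06, but adjusted p = 0.0735 with an estimated correlation), with GDF15 at -2.39 ± 0.068 and the cell cycle inhibitor gene CDKN1A at -1.61 ± 0.057. All 12 fibroblast and pericyte markers were lower on either scale (median -3.75, adjusted p = 5.88e-09, and 0.0168 with an estimated correlation), with COL3A1 of type III collagen at -8.65 ± 0.115 and POSTN, which encodes periostin, at -6.74 ± 0.0935. The basement membrane collagen gene COL4A1 (-8.95 ± 0.0822, 494-fold lower), CLDN11 (-8.75 ± 0.0577) and CCND2, which encodes cyclin D2 (-8.32 ± 0.143), were also lower. The U87vIII DMSO levels of CLDN11 (3.04), CCND2 (3.18) and COL3A1 (4.11), and that of COL4A1, lay within the range of the background controls, so these sizes too are lower bounds if the level is background.

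Lipid genes differed before treatment. Of 16 cholesterol biosynthesis enzymes 13 were higher and 1 lower in U87vIII on either scale (median 0.95, adjusted p = 9.11e-05, but adjusted p = 0.245 with an estimated correlation), with HMGCS1 higher by 1.49 ± 0.0594 (2.81-fold, adjusted p = 2.31e-10). INSIG1 was higher by 2.15 ± 0.0481 (4.43-fold, adjusted p = 1.23e-12), NPC1 by 3.30 ± 0.0699, LRP8 by 3.28 ± 0.072, SCD by 1.07 ± 0.0504 and NR1H3 by 1.66 ± 0.0954 (3.15-fold). The levels of NR1H3 in NHA (4.83), MYLIP in U87vIII (5.44) and ABCG1 in both cell types (5.06 and 4.65) lay within the range of the background controls. Of 17 fatty acid synthesis and desaturation genes 12 were higher and 3 lower on either scale (median 0.57, adjusted p = 0.017, but adjusted p = 0.152 with an estimated correlation). MYLIP differed by -1.07 ± 0.101 and ABCG1 by -0.41 ± 0.119 (adjusted p = 0.0086), while ABCA1 (-0.06, adjusted p = 0.282) and LPCAT3 (0.12 ± 0.0551, adjusted p = 0.0723) were not called. With the mean of its probe sets in place of the brightest, LPCAT3 read -0.12 (adjusted p = 0.0282). Of the LXR target genes 5 of 19 were higher and 6 lower on either scale, and the list was not called (median -0.01, mean 0.10, test direction up, adjusted p = 0.8). Of 22 lipid storage and lipolysis genes 8 were higher and 8 lower on either scale (median -0.05, mean -0.31, test direction up, adjusted p = 0.977), with the lipid droplet coat gene PLIN2 at -5.15 ± 0.127 (3.95 in U87vIII DMSO, within the range of the background controls).

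Glycolysis and hypoxia genes were higher in U87vIII with 14 of 25 higher and 5 lower on either scale (median 0.17, adjusted p = 0.0442, but adjusted p = 0.336 with an estimated correlation), a call lost without NHA DMSO 2, U87vIII DMSO 2 or U87vIII DMSO 3 (adjusted p = 0.0502, 0.0539 and 0.054). The other lists were not called. On either scale, members higher and lower were 6 and 3 of 12 for sterol uptake and sensing (adjusted p = 0.0726), 4 and 3 of 13 PPAR target genes (median -0.01, mean -0.17, test direction up, adjusted p = 0.736), 7 and 12 of 23 ATF4 and integrated stress response genes (adjusted p = 0.259), and 1 and 9 of 19 endoplasmic reticulum chaperones (adjusted p = 0.0726). They were 3 and 9 of 18 pro-apoptotic genes (adjusted p = 0.142), 7 and 11 of 23 NF-kB and inflammatory genes (adjusted p = 0.466), 11 and 5 of 22 interferon-stimulated genes (adjusted p = 0.111), 10 and 7 of 20 growth factor and MAPK output genes (adjusted p = 0.466) and 7 and 4 of 12 mesenchymal glioma markers (adjusted p = 0.245). For cell type markers they were 5 and 8 of 19 for astrocytes (5 and 9 adjusted over the list alone, adjusted p = 0.598), 2 and 7 of 14 for neurons (adjusted p = 0.357), 1 and 5 of 11 for the oligodendrocyte lineage (adjusted p = 0.0726), 1 and 3 of 13 for microglia and macrophages (median -0.18, mean 0.01, test direction down, adjusted p = 0.629), and 2 and 4 of 10 for endothelium (2 and 1 adjusted over the list alone, adjusted p = 0.449). The glutamate transporter gene SLC1A3 was higher in U87vIII (2.35 ± 0.0834, from 4.03 in NHA DMSO, within the range of the background controls) and the bicarbonate transporter gene SLC4A4 lower (-2.77 ± 0.0888). GFAP, the astrocyte filament protein, read 6.37 in U87vIII DMSO and 6.62 in NHA DMSO. Both levels lay close above the controls with 20 G or C bases (5.9 and 6.23).

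By limma 5699 genes were higher and 6511 lower in U87vIII DMSO than in NHA DMSO, 67.4% of the 18106 tested, with 1828 and 1337 differing at least 2-fold. The median of all genes lay at -0.08, and at -0.11 with the arrays shifted to a common median, so small baseline differences are relative to that centre.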

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

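The tests of a signal ceiling, of a trend within groups and of growth state were chosen after the patterns were seen, each with its bound set before its own result, while the regroupings of labels were set beforehand.

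Cholesterol biosynthesis enzymes rose in NHA by a median of 0.40 and not in U87vIII (0.02), and the test of the difference called the list at a median of -0.364. Outside the list 2439 genes were at least as bright in U87vIII DMSO as the median enzyme (10.1). Of these, 13 were called higher in U87vIII by 0.40 or more, which argues against a hard ceiling of the arrays at that level. A partial compression of bright signals would still let some genes rise, so this count cannot decide on it, and it stays open. Removing the leading within-group axis left a median of -0.364 (SD 0.01 over arrays left out). The difference over the other genes shifted along that axis by only 1.82, against a chance SD of 9.61. That axis therefore does not account for the pattern, and its removal could change little. A trend along other axes, or aligned with the groups, cannot be seen this way and stays open. The DMSO levels already differed (median 0.95 higher in U87vIII), a call lost at an adjusted p = 0.245 with an estimated correlation. A biological difference between the cell types and a difference in lipid supply stay open and were not tested, since the labels give no medium or serum.

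ATF4 and integrated stress response genes had a median of 0.15 in U87vIII (but adjusted p = 0.102 with an estimated correlation), -0.21 in NHA (0.0478) and a difference of 0.313 (0.0273). Removing the leading within-group axis left a median difference of 0.31 (SD 0.011 over arrays left out). The difference over the other genes shifted along that axis by only 1.9, against a chance SD of 9.6. That axis therefore does not account for the pattern, while a trend along other axes or aligned with the groups was not tested. For growth state of the dishes, arrays with higher mitosis genes were predicted to have lower ATF4 genes. The within-group deviations of the 12 arrays correlated instead at r = 0.63 (permutation p = 0.0434) and rho = 0.622 (permutation p = 0.0794). Without the 2 arrays farthest from the median of the mitosis score r was 0.432, and no other relation was computed. The labels do not say that the arrays of a group came from separate dishes, so these deviations may be technical. They cannot decide on growth state, which stays open. A biological difference between the cell types and a difference in nutrient supply at harvest stay open, and neither was tested.

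Mitosis and DNA replication genes rose in NHA (medians 0.25 and 0.16) and had lower medians in U87vIII (-0.04 and -0.09, but adjusted p = 0.59 and 0.102 with an estimated correlation), a difference of -0.288 for both lists together. With the leading within-group axis removed the median difference was -0.284 (SD 0.016 over arrays left out). The difference over the other genes shifted along that axis by only 1.8, against a chance SD of 9.59. That axis therefore does not account for the pattern, while a trend along other axes or aligned with the groups was not tested. The DMSO levels of both lists were far higher in U87vIII (medians 3.08 and 2.57), so the changes start from unequal levels in the cell types. A biological difference between the cell types stays open and was not tested.

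The test of the difference between the cell types picked out 66 genes with a higher and 113 with a lower effect in U87vIII, and 10 lists. The key genes were ABCA1 (0.53), ABCG1 (-1.44), MYLIP (1.04), SREBF1 (0.65), SCD (-0.50), HMGCS1 (-0.94) and INSIG1 (-0.65). Other named genes with positive differences were SPINK1 (2.36), ATP6V0D2 (1.47), ADAMTS5 (1.29), PNLIPRP3 (1.27), IL1B (1.20), PTGS2 (1.19) and TMEM156 (1.08), and those with negative differences ANO1 (-1.19), H1-1 (-1.08), SMAD6 (-1.02), SHROOM2 (-0.90), THBS1 (-0.90) and DIRAS3 (-0.87). In NHA SPINK1 (2.99 and 3.00 with DMSO and LXR-623), PNLIPRP3, ATP6V0D2, PTGS2 and TMEM156 read at or near background, so a fall there could not be seen, and a rise only above the background. The U87vIII levels of ABCG1 and ANO1 and the NHA levels of H1-1 and SMAD6 also lay within the range of the background controls. Single arrays ended some of these calls: SREBF1 without NHA DMSO 3 or NHA LXR-623 2 (adjusted p up to 0.0584), TMEM156 without NHA LXR-623 2 or U87vIII LXR-623 3 (up to 0.0556), and SMAD6 without U87vIII DMSO 2, NHA LXR-623 3, U87vIII LXR-623 2 or U87vIII LXR-623 3 (up to 0.0622). THBS1 lost its call without NHA DMSO 3, NHA LXR-623 1 or 2, or any U87vIII DMSO array (up to 0.0735), and H1-1 without any array but NHA DMSO 3, U87vIII DMSO 3 and U87vIII LXR-623 2 (up to 0.0735). The median differences of the other lists were 0.145 for LXR target genes, -0.0972 for fatty acid synthesis and desaturation, 0.0834 for endoplasmic reticulum chaperones, -0.324 for mitosis genes, -0.262 for DNA replication genes, 0.0871 for NF-kB and inflammatory genes, 0.0479 for glycolysis and hypoxia genes, and -0.14 for growth factor and MAPK output genes. With an estimated correlation 4 of the 10 lists kept their call: cholesterol biosynthesis enzymes, ATF4 and integrated stress response, mitosis genes and DNA replication genes. The others lost it: LXR target genes (adjusted p = 0.0961), fatty acid synthesis and desaturation (0.0989), endoplasmic reticulum chaperones (0.131), NF-kB and inflammatory genes (0.0941), glycolysis and hypoxia genes (0.0805) and growth factor and MAPK output genes (0.0561).

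Probe sets with no gene symbol, which the gene tests did not use, also responded: of 2473, 30 were higher and 16 lower in U87vIII, and 16 higher and 1 lower in NHA, by limma at an adjusted p under 0.05.

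The regroupings of labels gave these counts. In U87vIII 1 of the 10 splits of the 6 arrays, the real one, gave as many as 482 genes, and the highest other gave 6. In NHA 1 of 10 did (158 genes, highest other 0), and in the baseline comparison 1 of 10 (12210 genes, highest other 0). With 10 splits the share cannot go under 0.1, and so not under 0.05. For the difference of effects 2 of 100 drawn splits, the real one included, gave as many as 179 genes. That share is under 0.05, but the highest other gave more, 233. Relabelling within cell types also breaks the LXR-623 effect in each of them. It therefore cannot decide whether unequal effects arose by chance. The split with 233 genes put NHA DMSO 2 and U87vIII LXR-623 1 on the same side of the relabelled treatment. It had the largest shift of all drawn splits along the leading within-group axis (23.1), and whether that shift gave its count was not tested. The next highest of the others gave 164. The 8 splits that kept the U87vIII labels gave 54 to 164 genes. The 6 that kept the NHA arrays grouped as treated, with the labels as they were or swapped, gave 3 to 11. The other 85 gave from 0 to 233.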

How the results depend on the processing

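The alternatives that leave out both outlying arrays or remove the leading within-group axis were chosen after seeing the data, and all others were set beforehand. In the baseline comparison counts of genes stayed within 1.5 times those reported under the mean of probe sets, common-median and within-cell-type quantile normalization, trend and robust moderation, the model of 6 arrays and the block. In the other comparisons they did so under the mean of probe sets and both normalizations. Similar counts do not mean the same genes. Under the mean of probe sets 349 of 482 genes called in U87vIII, 101 of 158 in NHA and 118 of 179 for the difference were still called. Named genes and lists kept their direction and side of the threshold in 4072 and 1117 results, lost the call in 784 and 54, gained it in 3 and 24, and turned in 1 and 1. The arrays' signal over background limits small changes among dim genes: the background controls with 20 G or C bases read 5.87 to 6.23 and those with 13 read 3.00 to 3.09, while the dimmest 40% of genes lie under 5.94.

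With fewer arrays fewer genes were called, but not always fewer lists. With each array left out in turn, 174 to 242 genes were higher and 101 to 143 lower in U87vIII, 47 to 110 and 5 to 17 in NHA, 35 to 51 and 43 to 96 for the difference, and 5461 to 5616 and 5749 to 6466 at baseline. Genes higher in both cell types were 14 to 23 and lower in both 0 to 2, and lists called were 8 to 11 in U87vIII, 8 to 10 in NHA, 9 to 11 for the difference and 7 to 8 at baseline. Calls held without each single array for 219 of 482 genes in U87vIII, 47 of 158 in NHA, 70 of 179 for the difference and 10410 of 12210 at baseline, and the sign was kept for all. Only the 6 arrays compared gave 165 and 85 (higher and lower) in U87vIII and 30 and 2 in NHA. Without both outlying arrays 172 were higher in U87vIII, 59 and 13 higher and lower in NHA, 30 and 43 for the difference, and 15 and 0 in both cell types.

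Stricter thresholds by construction gave fewer calls. A 2-fold minimum left 11 and 0 in U87vIII, 3 and 0 in NHA, 11 and 4 for the difference, and 1828 and 1337 at baseline. An adjusted p under 0.01 left 138 and 77, 50 and 4, and 25 and 30 for the first 3, and 14 and 0 in both cell types. Where limma called none lower at least 2-fold, 2347 genes in U87vIII and 2504 in NHA had an unadjusted p under 0.05 in either direction.

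Testing every probe set by itself counted 464 and 345 probe sets in U87vIII, 185 lower for the difference, and 13702 and 15205 at baseline, where a gene can count several times. It counted fewer, 20 lower, in NHA, and the cause was not tested. Leaving out dim genes, so that fewer genes were tested, gave 286 and 59 in NHA, 100 and 204 for the difference, 4041 lower at baseline, and 58 and 7 in both cell types. Trend and robust moderation gave 467 and 288 in U87vIII, 270 higher in NHA, and 122 and 254 for the difference, and the cause was not tested. Removing the leading within-group axis gave 512 and 358 in U87vIII, 276 and 113 in NHA, 168 and 243 for the difference, and 57 and 11 in both cell types, and the cause was not tested.

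With the replicate number as a block 145 and 91 genes were called in U87vIII, 38 and 2 in NHA, 18 and 18 for the difference, and 13 and 0 in both cell types, with 224, 39 and 36 genes shared with those of the model without a block. Nothing in the labels says that the numbers pair the arrays, and the deviations did not either: arrays with the same number correlated at -0.19 to 0.089 in NHA, -0.27 to 0.29 in U87vIII and -0.3 to -0.073 between the cell types, and 1, 2 and 0 of 6 arrays correlated best with their own number. The block therefore spends degrees of freedom on a pairing that these arrays do not show. Under it 1 list each lost its call in U87vIII (mesenchymal glioma markers, adjusted p = 0.0666), NHA (endoplasmic reticulum chaperones, 0.0552) and at baseline (glycolysis and hypoxia, 0.0543).

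With an estimated correlation 3 lists were called in U87vIII, 4 for the difference and 3 at baseline, since correlated members carry less evidence. At baseline fry, which does not compare a list with other genes, called 20 lists. It called lipid storage and lipolysis lower (median -0.0519, adjusted p = 1.74e-05), where camera gave the other direction without a call, and the cause was not tested. LPCAT3 at baseline turned from 0.12 to -0.12 with the mean of its probe sets, whose values run from -0.504 to 0.12.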

Other observations

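The tests of the 3 wider gene sets below were chosen after single genes had been noticed, each with its bound set before its own result, and the genes of the next paragraph were chosen after their values were seen. The sets were tested on the same arrays in which those genes were noticed, and their p-values are not adjusted over sets. Those p-values are therefore no independent support for a hypothesis.

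Beyond the lipid lists, several genes rose in both cell types. RNF145, a ubiquitin ligase of the endoplasmic reticulum, rose by 0.50 in U87vIII and 0.50 in NHA, LPCAT1, a lysophospholipid acyltransferase, by 0.34 and 0.52, and TMEM135, a protein of peroxisomes and mitochondria, by 0.55 and 0.64. These calls held without each single array, with the highest adjusted p at 0.0383 (LPCAT1 in U87vIII without DMSO 3). EIF2AK3, which encodes the stress kinase PERK, rose by 0.35 in each cell type, but its NHA call was lost without NHA DMSO 2, DMSO 3, LXR-623 2 or LXR-623 3 (adjusted p up to 0.0873, without LXR-623 2). The interferon-induced GTPase gene GBP1 fell by 0.69 in U87vIII and by 0.30 in NHA, where its call was lost without any 1 of the 6 arrays (adjusted p up to 0.113, without LXR-623 3).

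Genes of the actin cytoskeleton and targets of SRF and YAP, which respond to actin and to cell shape, formed a first hypothesis: LXR-623 may lower a wider set of them in U87vIII than the 6 first noticed. Without those 6, the other 25 measured members had a median of -0.178 in U87vIII, with 8 lower, none higher and 17 not called. The set met the bound chosen for the hypothesis (camera p = 5.26e-14, and p = 0.000135 with an estimated correlation). The lower members included CCN2 (-0.66), CCN1 (-0.57), AMOTL2 (-0.56), the coagulation initiator F3 (-0.40) and CNN2, a calponin (-0.36), whose calls held without each single array. The calls of CRIM1 and VCL were lost without any 1 of the 6 U87vIII arrays (adjusted p up to 0.159 and 0.149). That of FSTL1 was lost without DMSO 1, DMSO 2, LXR-623 2 or LXR-623 3 (up to 0.0714). In NHA the median was -0.05 with none called (p = 0.00412, and p = 0.0318 with an estimated correlation). The fibroblast and pericyte markers that fell in U87vIII hold ACTA2 and TAGLN, 2 genes of the same kind that were among the 6 noticed and were not called in U87vIII. Whether cell density or attachment differed between dishes is not given by the labels and stays open.

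Lysosome and V-ATPase genes formed another, that LXR-623 may raise a wider set than ATP6V0D2 alone. The other 26 measured members had a median of 0.139 in U87vIII, with 6 higher, none lower and 20 not called. The set met the bound chosen for the hypothesis (camera p = 4.54e-15, and p = 0.00439 with an estimated correlation). The higher members included GPNMB, a lysosomal glycoprotein (0.55), the protease gene CTSD (0.30) and the sialidase gene NEU1 (0.28), whose calls held without each single array. GPNMB read 0.43 in NHA (adjusted p = 0.0614). The call of ATP6V1B2 was lost without any 1 of the 6 U87vIII arrays (adjusted p up to 0.154). That of CTSB was lost without DMSO 2, DMSO 3, LXR-623 2 or LXR-623 3 (up to 0.0971), and that of MCOLN1 without DMSO 1, LXR-623 1 or LXR-623 2 (up to 0.0709). In NHA the median was 0.03 with none called (p = 0.0395, and p = 0.333 with an estimated correlation).

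Replication-dependent histone genes gave no decision on the third, that LXR-623 may lower a wider set than the 3 noticed: the other 51 had a median of -0.0198 in U87vIII, with 1 lower and 50 not called (camera p = 0.146, and p = 0.179 with an estimated correlation). In NHA their median was -0.08 with none called (p = 0.00114, and p = 0.0108 with an estimated correlation). The differences of these sets between the cell types were not tested.

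Probe sets of a gene did not always give the same size of change. ABCA1 had 3, with 2 called in each cell type, from 0.19 to 2.58 in U87vIII and -0.23 to 1.77 in NHA. The 3 of MYLIP were called in both cell types, from 0.97 to 2.19 in U87vIII and 0.65 to 1.16 in NHA, and the 4 of SCD ran from 0.41 to 0.94 and 0.92 to 1.36, with 3 and 4 called. SREBF1 had 3, from 0.25 to 1.24 in U87vIII with 2 called, and 0.23 to 0.59 in NHA with 1 called. LPCAT3 had 5, from 0.12 to 0.90 in U87vIII and -0.11 to 0.65 in NHA, with 4 called in each. Among called genes with several probe sets, all others had the same sign for 309 of 370 in U87vIII and 90 of 121 in NHA, and none had another probe set called in the opposite direction. At baseline 500 of 8554 had. Probe sets with several symbols, 1832 in all, were higher and lower for 12 and 10 in U87vIII and 4 and 1 in NHA. At baseline 611 probe sets with no symbol were higher and 787 lower, and for the difference of effects 8 and 11.

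Signal ratios between the 3' and 5' probe sets of the control transcripts GAPDH and ACTB, a measure of RNA integrity and labelling, were small. For GAPDH they were 0.017 ± 0.043 and 0.034 ± 0.028 in NHA (DMSO and LXR-623) and 0.084 ± 0.019 and 0.071 ± 0.024 in U87vIII (log2, SD, n = 3). For ACTB they were 0.056 ± 0.026 and 0.1 ± 0.03 in NHA and 0.18 ± 0.015 and 0.21 ± 0.031 in U87vIII.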
